A study of Homo sapiens with 4 samples.

How the data were processed

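The series holds 4 m6A-immunoprecipitated RNA libraries from HEK293 cells, a human embryonic kidney line. MeRIP-seq captures fragments of RNA with an antibody against N6-methyladenosine (m6A), a methyl mark on adenosines of mRNA and other RNA, and sequences what was bound. Cells carried either a slow-elongating RNA polymerase II (RNAPII) or the control form labelled wild type (WT), with 2 libraries of each. Per the labels' protocols, all cells received doxycycline at 1 µg/ml for 24 h and then doxycycline with α-amanitin, an RNAPII inhibitor, at 2.5 µg/ml for 42 h. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so the spread between them may be technical.

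Per the submitters' processing notes, reads were aligned with TopHat2 to hg19. The TopHat2 version and its handling of reads with several equal alignments are not given in the sources used here. Per the file headers, peaks were called with MACS version 2.1.1.20160309 at a q-value limit of 0.01, with 1 IP library as treatment and the same-numbered IP library of the other condition as control. Each of the 2 pairs was called in both directions, which gives 4 lists, and replicates were not pooled. No input library entered these calls, so a region can be listed because its methylation differed, because its transcript level differed, or both. Input libraries were not analysed here. The headers give reads of 65 bp, a small and a large window for the local background of 1000 and 10000 bp, and at most 1 read kept per position and strand.

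The deposited pileup is a coverage signal, the number of extended fragments over the summit in the treatment library after duplicate removal; per the file headers the larger library was scaled down to the smaller, so pileups of WT libraries are scaled and those of slow libraries are not. Undoing the scaling gave whole fragments, within 0.05, for all 915 and 707 WT-higher peaks. The deposited fold ratio is the treatment pileup over the control background, which equals (pileup + 1) over (background + 1) with the pseudocount of 1 that the caller uses by default. The authors' lists also carry p-values and q-values as −log10, in 2 columns whose header names were lost to a spreadsheet error as deposited; they were identified from the caller's column order, from the first exceeding the second in every row, and from the second lying above the limit. The control background used below was computed from pileup and fold, and limits on it allow 0.01 fragments for rounding. A fold is the caller's value for 1 library against 1 library and has no error of its own.

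Depth was taken from the file headers. Duplicate removal left 698050 and 547402 reads of 16417503 and 8804552 in the slow libraries of pairs 1 and 2, and 1695246 and 1136611 of 20556035 and 15072336 in the WT libraries. The headers give redundant rates of 96% and 94% for the slow libraries and 92% for each WT library. The ratio of WT to slow reads was 1.25 and 1.71 before and 2.43 and 2.08 after duplicate removal; the ratio after removal is called the depth ratio below. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. The limit given beside a count of 0 is instead 3 counts of the total, which is lower than the exact two-sided bound.

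Peaks are called slow-higher or WT-higher after the library that served as treatment. Peaks of 2 lists were shared when they overlapped by at least 1 bp. A reproducible region is a connected group of peaks of the same direction from both pairs with no overlapping peak of the opposite direction; its fold in each pair is that of its highest peak. Peaks or regions no more than 20 kb apart were chained, and each chain is called a locus, or a dense stretch where 1 list had at least 10 peaks in it. Shares were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment within each family. Peaks and loci are not replicates of the cells: these tests compare lists. Over the 2 pairs, an exact sign-flip test of the slow-higher share against 50% cannot give a two-sided p below 0.5. Agreement of folds was tested with 100000 arrangements (permutations and the observed order), shared peaks by chance with 100 shifts of a whole list by 10 to 1000 kb, and regular spacing of summits with 999 random placements. Spacing was tested with 2 statistics: the phase of all summits at 1 period, which was tried first, and the share of summits with another summit 1 fixed distance further on, which was added after the first had been seen. Their p-values were adjusted together. The overlap rules were tested on simulated data of 1000 peaks per list, where all 7 settings returned the number planted. On 100 simulated sets of 24 regularly spaced summits the phase statistic called 99 and the distance statistic 100. Of 100 random sets they called 4 and 5. The spaced sets held 2 summits per period, so they do not show the power of either statistic where a period holds more summits. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

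The reference table at hand is of another assembly (GRCh38) than the peaks, and the lists carry no gene names. Peaks are therefore given by hg19 position, 1-based as deposited, and no gene, exon or UTR is named. The comparisons planned on transcript region, stop codon distance, DRACH motif, gene structure, gene lists and genes with both directions were not run for this reason. The regions named by rule, fixed before the data were examined, are the 6 per direction with the highest value of the smaller of the 2 pairs' folds. The chromosome comparison, the dense stretches and the limit of 10-fold were chosen after the data were seen. Alternatives fixed before the data were examined were a −log10 q of at least 5, a fold of at least 2, a reciprocal overlap of at least 50%, summits within 100 bp, keeping regions with opposite peaks, and each pair left out. Leaving out dense stretches, chromosome Y, the mitochondrial genome and unplaced contigs, and leaving out folds up to the depth ratio, were added afterwards.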

Results

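The study asked how m6A maps differ between cells with normal and slow elongation by RNAPII. The deposited data compared m6A-immunoprecipitated libraries of the 2 conditions directly, in 2 same-numbered pairs, each in both directions. The 4 libraries kept between 547402 and 1695246 reads after duplicate removal, and both slow libraries were shallower than their WT partners.

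More regions were enriched in the slow library than in the WT library in both pairs. In pair 1, 1884 peaks were slow-higher and 915 were WT-higher, a share of 67.3% slow-higher (95% interval 65.5% to 69.0%). In pair 2, 1383 peaks were slow-higher and 707 WT-higher, a share of 66.2% (95% interval 64.1% to 68.2%). The mean share over the pairs was 66.7% ± 0.804 (SD, n = 2). Slow-higher peaks covered 398245 bp in pair 1 and 298120 bp in pair 2, against 189188 bp and 147142 bp for WT-higher peaks. The median fold did not set the directions apart, at 6.58 and 6.83 for slow-higher and 6.89 and 7.0 for WT-higher peaks in pairs 1 and 2. The highest folds were slow-higher, at 41.2 and 63.4 against 26.2 and 28.0, or at 39.6 and 36.4 without dense stretches, chromosome Y, the mitochondrial genome and unplaced contigs. After scaling, 1 background fragment counted 0.412 and 0.482 at slow-higher peaks of pairs 1 and 2, and 1 at WT-higher peaks. Folds at low background are therefore not on an equal footing between the directions. An exact sign-flip test of the slow-higher share of peaks against 50% gave a two-sided p of 0.5, the smallest that 2 pairs can give. The excess of slow-higher peaks was smaller without dense stretches, chromosome Y, the mitochondrial genome and unplaced contigs (described further on), at 64.1% and 61.8%.

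**Figure D1:**
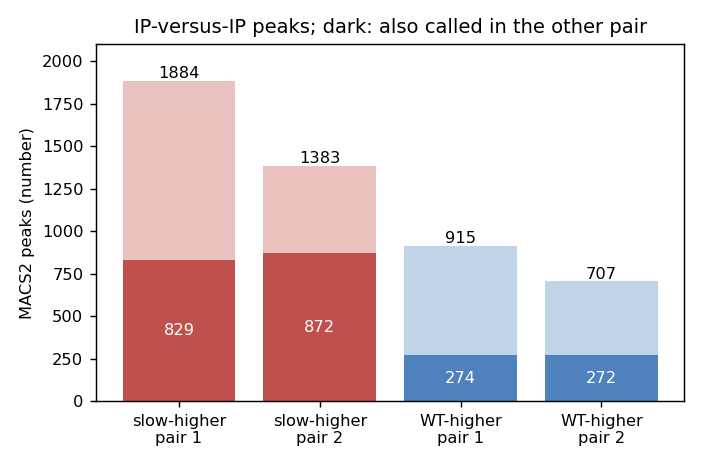
Number of MACS2 peaks (vertical axis) in each list, by direction and pair; the dark part of each bar is the peaks that overlap a peak of the same direction in the other pair. Slow-higher lists hold 1884 and 1383 peaks, and WT-higher lists 915 and 707.

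A part of each list recurred in the other pair, always in the same direction. In the slow-higher lists, 829 of 1884 peaks of pair 1 (44.0%) and 872 of 1383 peaks of pair 2 (63.1%) overlapped a slow-higher peak of the other pair. In the WT-higher lists the figures were 274 of 915 (29.9%) and 272 of 707 (38.5%). In all 4 lists, 0 peaks overlapped the opposite list of the other pair, which allows a share of up to 0.159% in the largest list and 0.424% in the smallest (3 peaks of the list). The difference between same-direction and opposite overlap passed Fisher's exact test in each list, the largest of the 4 adjusted p-values being 2.13e-93, though the same-direction and opposite lists differed in length. The test also treats both overlaps of the same peaks as separate samples, so its p-values are not exact. When a whole list was shifted at random, the mean number of shared peaks was 3.71 and 5.38 for the slow-higher and 0.1 and 0.21 for the WT-higher lists. The highest numbers in a single shift were 69 and 57, and 1 and 2. Shifts do not keep peaks within transcribed sequence, so they can understate sharing by chance. Slow-higher peaks were shared more often than WT-higher peaks, by 14.1 percentage points in pair 1 (Fisher's exact test, adjusted p = 8.59e-13) and 24.6 in pair 2 (adjusted p = 6.15e-26). Without dense stretches, chromosome Y, the mitochondrial genome and unplaced contigs, the differences were 10.0 and 18.9 percentage points. The slow-higher lists were also longer than the WT-higher lists, which was not allowed for. Of peaks with a −log10 q of at least 10, 64.9% and 80.4% of slow-higher and 46.8% and 51.6% of WT-higher peaks were shared. Below that value the shares were 28.2% and 47.0%, and 24.5% and 33.8%. A peak missing from the other pair was not called at that pair's depth and cannot be read as absent.

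Joining the pairs gave 810 reproducible slow-higher regions in 506 loci and 270 reproducible WT-higher regions in 229 loci, and 0 regions of either direction were removed for an opposite peak. Slow-higher loci made up 68.8% of the reproducible total (95% interval 65.4% to 72.2%), and 68.2% with the same sequence set aside. Among all loci of a pair the share was lower, at 60.3% in pair 1 (1128 against 744) and 58.9% in pair 2 (841 against 586), also below the shares of peaks. The slow-higher regions had a median fold of 7.79 in pair 1 and 7.63 in pair 2, the WT-higher regions 7.21 and 7.16. Regions at least 10-fold in both pairs were 166 of 810 slow-higher (20.5%) and 23 of 270 WT-higher (8.52%), a difference that passed Fisher's exact test (p = 3.05e-06). With that sequence left out, it was 88 of 643 (13.7%) against 23 of 270 (Fisher's exact test, p = 0.0345). As a background fragment weighs less at slow-higher than at WT-higher peaks, scaling may add to this difference, which was not tested. Folds of the same region in the 2 pairs were correlated across slow-higher regions (Pearson's r of log2 fold 0.81, Spearman's rho 0.74) and less closely across WT-higher regions (0.53 and 0.43). With that sequence left out, the slow-higher values were 0.73 and 0.64, and the WT-higher values were unchanged. Each of these correlations had an adjusted permutation p of 1e-05, the smallest that 100000 arrangements can give, and regions are not independent replicates.

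**Figure D2:**
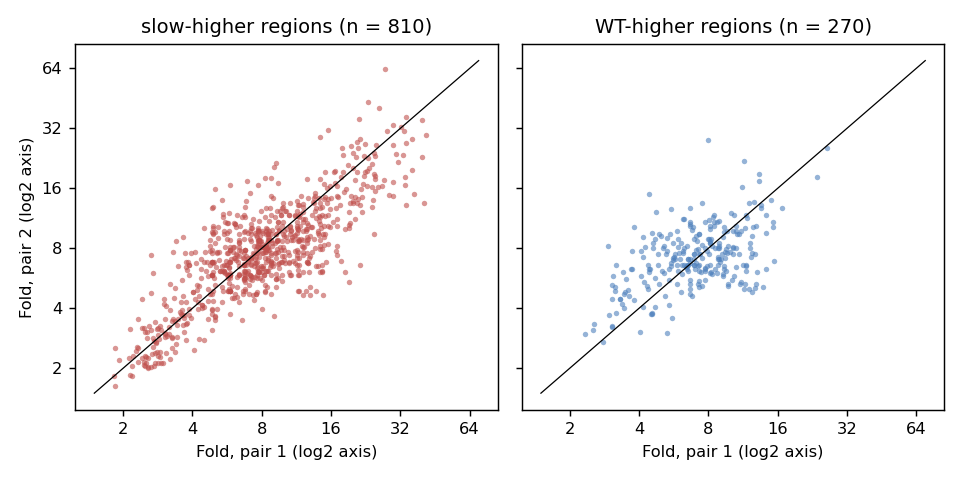
Fold of each reproducible region in pair 1 (horizontal axis) and pair 2 (vertical axis), both on log2 axes without unit, for 810 slow-higher and 270 WT-higher regions; the line marks equality. Slow-higher regions extend to higher folds in both pairs than WT-higher regions.

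The slow-higher region with the highest reproducible fold lay on chromosome 20 from 57465116 to 57465511. It was 39.6-fold higher in pair 1, with 66 slow fragments at the summit, and 35.3-fold higher in pair 2, with 63 fragments. The region on chromosome 19 from 11200805 to 11201705 was 34.0-fold and 36.4-fold higher, with 61 and 53 fragments. On chromosome 11, the region from 1317808 to 1318546 was 29.7-fold and 33.2-fold higher, with 41 and 33 fragments. The 3 other regions named by the rule all lay in 1 dense stretch of chromosome 19. From 37770074 to 37770524 the folds were 32.4 and 32.6, from 37790220 to 37792526 they were 33.1 and 31.0, and from 37779328 to 37779857 they were 41.2 and 29.6. At the second of these, the summits of the pairs lay at 37792220 and 37790374, so the 2 folds describe different parts of the region. The WT background at all 6 regions was at most 2.47 fragments after scaling, so these folds depend on the pseudocount of 1.

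The WT-higher regions with the highest reproducible folds were adjacent on chromosome 14. From 23588740 to 23591097 the WT library was 26.2-fold higher in pair 1, with 125 WT fragments at the summit against a slow background of 1.00, and 25.5-fold higher in pair 2, with 104 fragments. From 23587546 to 23588638 the folds were 23.8 and 18.3, with 113 and 74 fragments. These 2 regions belonged to a run of WT-higher peaks from 23583304 to 23591800 that held 8 peaks in pair 1 and 5 in pair 2. The other 4 named regions were smaller in fold. The region on chromosome 4 from 77675548 to 77675789 was 14.9-fold and 14-fold higher in WT. On chromosome 12, from 65268924 to 65269566, the folds were 13.3 and 17.4. On chromosome 2, from 20870687 to 20871113, they were 13.3 and 18.8. On chromosome 10, from 38118057 to 38118318, they were 13.5 and 13.2. The slow background at these 6 regions was at most 1.00 fragment, so these folds depend on the pseudocount of 1 as well.

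Runs of WT-higher peaks held few peaks each. Besides the chromosome 14 run, 6 others held at least 4 WT-higher peaks in both pairs, chosen after their values were seen. They included chromosome 1 from 152276175 to 152285090 with 7 and 5 peaks, chromosome 16 from 89783750 to 89804535 with 5 and 4, and chromosome 9 from 138376606 to 138379968 with 4 and 4. Chromosome X held 2 of them, from 84498966 to 84526820 and from 112021600 to 112066125, each with 5 and 4 peaks. No WT-higher list held a stretch of 10 peaks.

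A minority of slow-higher peaks lay in 12 dense stretches, 236 of 1884 in pair 1 (12.5%) and 225 of 1383 in pair 2 (16.3%), against 0 WT-higher peaks. The 2 richest lay on chromosome 19. From 36759307 to 36800430, 41.1 kb held 52 slow-higher peaks in pair 1 and 62 in pair 2, with median folds of 19.9 and 14.4. From 37759760 to 37797177, 37.4 kb held 32 and 57 peaks, with median folds of 22.7 and 17.2. Together they gave 84 of the 1884 slow-higher peaks of pair 1 (4.46%) and 119 of the 1383 of pair 2 (8.60%). WT-higher peaks numbered 0 in both stretches in both pairs. On chromosome X from 114960572 to 115004213 pair 1 had 27 slow-higher peaks with a median fold of 8.13, and pair 2 had 5 with a median fold of 8.88. Further on chromosome 19, the stretches from 48407563 to 48455753 and from 50596711 to 50640500 each had 10 peaks in each pair. Their median folds were 8.32 and 7.07 in the first and 7.94 and 8.85 in the second.

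**Figure D3:**
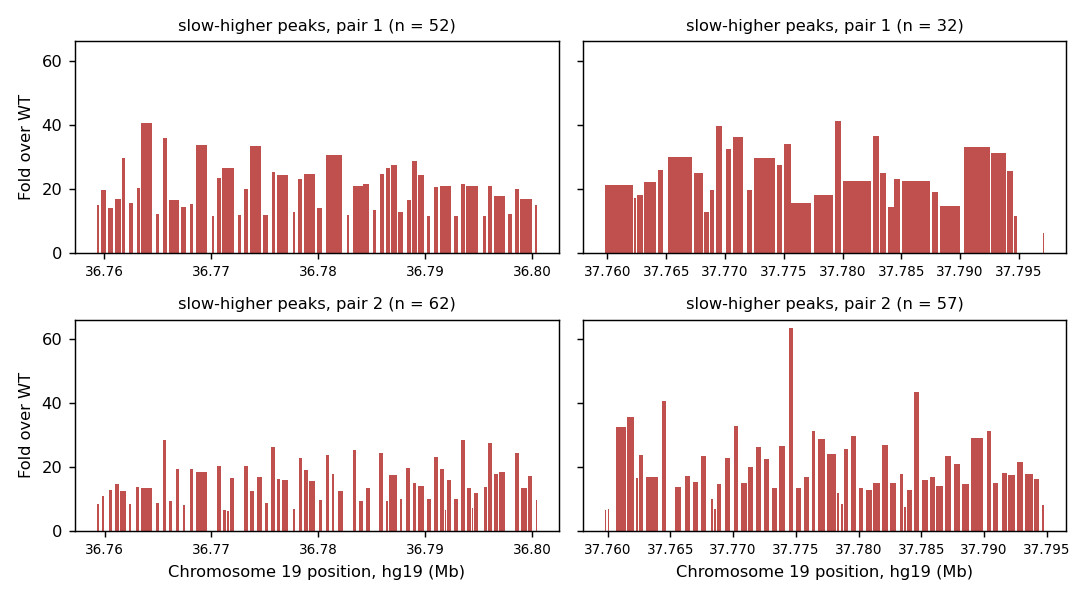
Slow-higher peaks in the 2 dense stretches of chromosome 19 (left and right columns), with hg19 position in Mb on the horizontal axis and fold over WT, without unit, on the vertical axis; rows are pairs 1 and 2, bar width is peak length. Peaks recur along the whole of each stretch in both pairs, 52 and 62 in the left and 32 and 57 in the right.

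Every peak called on the mitochondrial genome and on the unplaced contig chrUn_gl000220 was slow-higher. The mitochondrial genome, which mitochondrial RNA polymerase and not RNAPII transcribes, carried 18 slow-higher and 0 WT-higher peaks in each pair. Their median folds were 2.48 and 2.79, beside depth ratios of 2.43 and 2.08, and 8 of 18 in pair 1 and 0 of 18 in pair 2 lay at or below the depth ratio. The contig chrUn_gl000220, which carries ribosomal RNA gene sequence, had 30 slow-higher peaks in pair 1 and 24 in pair 2, and 0 WT-higher peaks. At its 22 and 15 peaks with a WT background of at least 20 fragments, median folds were 2.89 and 2.12, and 3 and 7 peaks lay at or below the depth ratio. At its other 8 and 9 peaks they were 7.38 and 7.29. Summits recurred 43972 bp apart on this contig in pair 1 (10 matches within 30 bp among 30 summits) and 43974.5 bp apart in pair 2 (6 among 24). On chromosome Y, 17 of 21 slow-higher summits of pair 1 and 16 of 20 of pair 2 had a slow-higher summit on chromosome X at an offset of 50000 bp within 30 bp. X and Y share pseudoautosomal sequence at their ends, so these peaks may count the same reads on both chromosomes and need not come from Y. The dense stretches include chromosome X from 295972 to 313764 and chromosome Y from 245972 to 269259, so they may count the same sequence in both places.

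**Figure D4:**
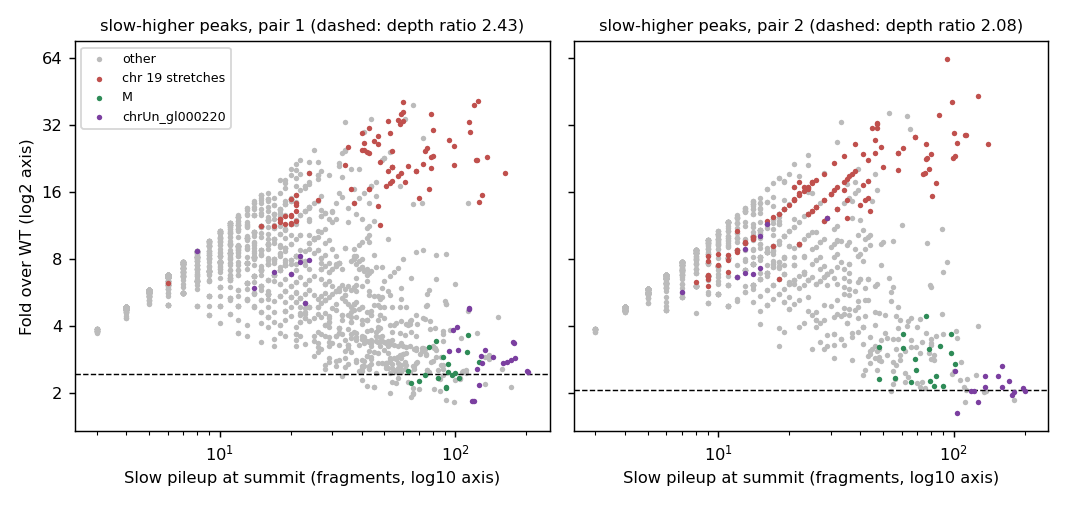
Fold over WT (vertical, log2 axis, without unit) against slow pileup at the summit in fragments (horizontal, log10 axis) for every slow-higher peak of each pair; colours mark the mitochondrial genome (M), contig chrUn_gl000220 and the 2 chromosome 19 stretches, and the dashed line is the depth ratio. Mitochondrial peaks lie around the line in pair 1 and above it in pair 2, with median folds of 2.48 and 2.79, and the chromosome 19 stretches lie above it, with median folds of 20.8 and 16.2.

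Differences between the directions in their spread over chromosomes depended on the unit and the settings. Counted as loci, so that a dense stretch counts once, chromosome 12 held 14 of 506 reproducible slow-higher loci (2.77%) and 20 of 229 WT-higher loci (8.73%), and this was the 1 class of 26 to pass Fisher's exact test (adjusted p = 0.0235). Among all loci of a single pair, the difference was smaller, at -3.98 percentage points in pair 1 and -2.58 in pair 2 (slow-higher minus WT-higher). It passed Fisher's exact test in pair 1 but not in pair 2. On reproducible loci it did not pass Fisher's exact test with a −log10 q of at least 5 (adjusted p = 0.0989), with 50% reciprocal overlap (0.0651) or with summits within 100 bp (0.0639). Under these last 3 settings the size was similar, with slow-higher minus WT-higher at -5.97 percentage points as first given and at -5.19, -5.95 and -5.64 under them. Chromosomes 19, 20 and 2 held larger shares of the slow-higher loci and did not pass on reproducible loci. By Fisher's exact test, chromosome 19 held 12.5% against 5.68% (adjusted p = 0.0712), chromosome 20 held 4.74% against 0.873% (adjusted p = 0.0712) and chromosome 2 held 6.32% against 2.62% (adjusted p = 0.166). In the larger sets of all loci of a pair, each of the 3 passed in both pairs. The adjusted p-values of Fisher's exact test in pairs 1 and 2 were 2.75e-05 and 0.00873 for chromosome 19, 0.000619 and 0.000699 for chromosome 20, and 6.01e-05 and 0.000699 for chromosome 2. Chromosome 4 was lower among slow-higher loci and passed Fisher's exact test in both pairs (adjusted p = 0.000538 and 0.0263), but not on reproducible loci (adjusted p = 0.166).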

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

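Of 105 alternatives to the main comparisons, none reversed a direction, none lost a test that had passed, and 13 moved an untested value beyond its interval or its spread between pairs, or a count by over 1.5 times. A tested difference, the excess of slow-higher regions at least 10-fold in both pairs, stayed past its threshold and shrank by over 1.5 times. With a −log10 q of at least 5, the slow-higher share rose to 71.7% and 69.0% in pairs 1 and 2, the reproducible WT-higher regions numbered 176, and the mean of the pairs' median folds was 8.13 for slow-higher (7.71 without this limit) and 8.06 for WT-higher regions (7.18 without it). Without dense stretches, chromosome Y, the mitochondrial genome and unplaced contigs, an alternative added after the data were seen, the slow-higher share was 64.1% and 61.8%, the median fold of slow-higher regions 7.38, and that excess 5.17 in place of 11.98 percentage points. With only folds above the depth ratio, also added afterwards, the median fold of slow-higher regions was 7.89. Leaving out pair 1 or pair 2 leaves nothing to reproduce, so the region counts become those of 1 list, 1383 to 1884 slow-higher and 707 to 915 WT-higher. Shares of peaks found in the other pair stayed past their test but fell below their intervals: in slow-higher pairs 1 and 2 and WT-higher pairs 1 and 2, to 36.78%, 50.1%, 25.4% and 32.8% with 50% reciprocal overlap, and to 40.02%, 54.5%, 26.3% and 34.1% with summits within 100 bp. So did the WT-higher share of pair 2 at a −log10 q of at least 5 (32.1%), and the slow-higher shares without dense stretches and the other sequence set aside (39.95% and 57.3%). The chromosome 12 difference no longer passed with a −log10 q of at least 5, with 50% reciprocal overlap and with summits within 100 bp, at adjusted p-values of 0.0989, 0.0651 and 0.0639, though its size stayed similar; the cause was not tested. Without dense stretches and the other sequence set aside, chromosomes 19 and 20 passed on reproducible loci, each at an adjusted p of 0.0478. The region on chromosome 19 from 37790220 to 37792526 had a smaller fold of 17.5 when summits had to lie within 100 bp. Values are within pairs by construction, and the sign-flip test is over the pairs; no paired analysis was possible in the sense of a fit with and without a replicate block, because the lists hold no values per library to fit. For a mean of 2 pairs, leaving out either moves it by less than 1 SD by arithmetic, which says nothing on its stability. Alternatives on annotation, stop codon distance and motif were not run, since no annotation of the build was used here. Depth limits the small peaks. The control background was under 1 fragment at 57.8% and 69.0% of slow-higher and 57.3% and 50.8% of WT-higher peaks. There the fold is largely set by the pseudocount. A single WT fragment, scaled to 0.412 or 0.482, falls under this limit, while a single slow fragment does not. The shares of the 2 directions are therefore not comparable, and more WT-higher peaks depend on the pseudocount than this limit counts.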

Other observations

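All tests in this part were chosen after the results they concern had been seen. Slow-higher loci lay more often in the first 5 Mb of a chromosome. Over chromosomes other than the acrocentric 13, 14, 15, 21 and 22, Y and the mitochondrial genome, 61 of 415 reproducible slow-higher loci outside dense stretches (14.7%) and 15 of 199 WT-higher loci (7.54%) started there (Fisher's exact test, adjusted p = 0.0125). Among such loci of pair 1 alone the shares were 13.05% and 6.25% (Fisher's exact test, adjusted p = 3.3e-05), and in pair 2 they were 13.4% and 8.48% (adjusted p = 0.0125). The test pooled chromosomes, and 5 Mb is a larger part of a short chromosome than of a long one. Slow-higher loci held larger shares on the short chromosomes 19 (12.5% against 5.68%) and 20 (4.74% against 0.873%), but also on the long chromosome 2 (6.32% against 2.62%). The spread over chromosomes was therefore not separated from position. The distal ends of the chromosomes were not examined, and no sequence was at hand to compare GC content.

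Several dense stretches had summits at regular distances, and the answer depended on the statistic. Spacing was tested in 16 lists of at least 10 peaks, and the lists of the mitochondrial genome and contig chrUn_gl000220 were left out. The statistic tried first, the phase of all summits at 1 period, passed in 3 of the 16. The share of summits with another summit 1 fixed distance on, chosen after that result, passed in 9, which include those 3. Each pass had a permutation p of 0.001, the smallest that the random placements could give, and an adjusted p of 0.00267 over all 32 tests. Both statistics passed on chromosome X from 114960572 to 115004213 in pair 1. There 73.9% of the summits had another 5980 bp on, near the longest distance tried, 6000 bp. The phase period was 2985 bp. The distance is close to a whole multiple of that period, so the 2 statistics need not describe different spacings. Both statistics also passed on chromosome 19 from 48407563 to 48455753, with 88.9% of summits matched at 5340 bp in pair 1 and at 5330 bp in pair 2. From 50596711 to 50640500 only the distance statistic passed, at 5320 bp in both pairs (55.6% and 66.7% matched), and the phase did not (adjusted permutation p = 0.0869 and 0.0788). Neither statistic passed in the stretches on chromosomes 16 and 20, at 153569627 on chromosome X, and at the start of chromosomes X and Y.

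The densest stretches of chromosome 19 are the first pattern to follow up. Reads shared between tandem copies are a candidate explanation for the number of peaks: 64.6% of summits in the stretch at 36759307 recurred 2520 bp on in pair 1 and 65.5% at 2510 bp in pair 2, against at most 43.6% and 40.7% in random placements, and that at 37759760 recurred at 5050 bp in both pairs (55.6% and 83.7%). The phase statistic, tried first, found no period in either stretch (permutation p = 0.917 and 1 in the first, 0.426 and 1 in the second, unadjusted), so this rests on the statistic chosen later and on pileups, which differed by a median factor of 1.13 at that distance in the first stretch against 1.70 and 2.00 between any 2 summits. The simulated sets held 24 summits, 2 per period, so the power of the phase statistic in stretches with more summits was not tested. Duplicate removal with scaling of the larger library was argued against as the source of the direction. Slow pileup over unscaled WT background had a median of 13.4 (quartiles 11.3 to 22.8) in pair 1 and 16 in pair 2, where that explanation would give about 1. This bound was written after the values were seen, and the stretches were chosen for their many slow-higher peaks. Whether reads map to several copies in these stretches, and whether methylation, transcript level or DNA copy number differed between the cells, was not tested and stays open.

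The second pattern is the set of slow-higher peaks on the mitochondrial genome and at high coverage on contig chrUn_gl000220. Duplicate removal followed by scaling could produce it, since with 1 read kept per position an abundant RNA reaches a similar pileup in both libraries, and the WT value is then divided by the depth ratio. With the scaling undone, slow pileup over WT background should lie at 1; it had a median of 1.04 on the mitochondrial genome in pair 1 (quartiles 0.974 to 1.203) but 1.37 in pair 2 (1.15 to 1.61), and on the contig 1.2 in pair 1 (1.09 to 1.38) but 1.03 in pair 2 (0.988 to 1.13). With the quartiles spanning 1 in a single pair each, this processing and a difference between the cells cannot be told apart, and against the 232 and 248 that 1 read per position and strand would allow, pileups reached 126 and 101 on the mitochondrial genome and 204 and 200 on the contig. Slow-higher peaks with a control background of at least 20 fragments numbered 127 and 69 over all chromosomes, or 86 and 39 without the sequence set aside, and WT-higher peaks 3 and 4 in both sets.

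The third pattern is the excess of slow-higher peaks. The sequence set aside does not account for the whole of it: without dense stretches, chromosome Y, the mitochondrial genome and unplaced contigs the slow-higher share was 64.1% (62.3% to 66.01%) in pair 1 and 61.8% (59.5% to 64.02%) in pair 2, and 59.9% and 58.4% of loci. Scaling of the larger library to the smaller cannot be told apart from a difference between the cells. Among peaks with a fold above the depth ratio the share was 66.9% and 66.02%, but WT-higher candidates that the scaling removed are not in the lists. Library complexity goes the same way as the condition, since both slow libraries kept fewer reads than their partners, and a change in m6A and a change in transcript level stay open alike.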
